A study of Xenopus laevis and Xenopus tropicalis with 12 samples.

How the data were processed

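RNA was measured in 12 libraries of animal and vegetal oocyte hemispheres dissected by hand, 8 of X. laevis and 4 of X. tropicalis. Per the labels, total RNA was extracted with proteinase K and phenol-chloroform and precipitated with lithium chloride and ethanol, and libraries followed standard Illumina protocols. The submitters' processing notes name Bowtie2 2.1.0, edgeR and DESeq, the last pair with no version; the genome build and the counting program are not given in the sources used here. The deposited file of each library holds raw read counts for 28165 gene models, with no normalization. Libraries of both species carry the same X. tropicalis model identifiers, so X. laevis homeologous L and S copies have no separate values. Paralogs with near-identical sequence may share reads, and strand was not stated, so values of overlapping or antisense genes are uncertain. A deposited annotation table paired all 28165 models with their records. Of these, 14513 (51.5%) had a usable symbol, 12886 had none and 766 were marked unknown. A table of X. laevis genes (assembly X. laevis v10.1) was used only to count genes with both an L and an S copy. The other deposited list of identifiers was not used here.

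Groups were species and hemisphere, taken from the labels. The replicate of X. laevis was the batch (2 batches from each of 2 females) and that of X. tropicalis the female, whose number the labels give for each library. The labels tie both hemispheres to a batch or female, which was kept as a block in the reported tests. Deviations of paired libraries from their group means correlated between 0.701 and 0.844 in X. laevis and at 0.797 in X. tropicalis. Pairs across X. laevis females correlated between -0.845 and -0.709, while libraries of the other batch of the same female correlated between 0.755 and 0.833. No libraries were treated as copies of each other, since the chi-square per degree of freedom between libraries of a group was at least 12.1. In X. laevis the p-values rest on the spread between 4 pairs of libraries from 2 females and on the spread pooled across genes. X. laevis batches of 1 female are not separate animals. In X. tropicalis, with 2 females, the p-values of the hemisphere test rest almost entirely on the spread pooled across genes. That test had 1 residual degree of freedom per gene and a prior of 162.

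Counts were analysed with edgeR 4.0.16 in R 4.3.3. Models were filtered with filterByExpr per species (14517 kept in X. laevis, 12916 in X. tropicalis), scaled with TMM factors and tested with the quasi-likelihood F test. Adjusted p-values are by Benjamini-Hochberg. A model was called enriched at an adjusted p under 0.05 and at least 2-fold. Standard errors of log2 fold changes were derived from the F statistic. The species interaction used models that passed the filter in both species (11688), TMM factors per species and 6 blocks, and the female interaction the 8 X. laevis libraries with 4 blocks. The species interaction was fitted with 1 spread per model for both species. Fitted apart, the common biological coefficient of variation was 0.132 in X. laevis and 0.0468 in X. tropicalis, so its standard errors and calls assume an equal spread. CPM values use TMM-scaled library sizes, and a prior count of 2 was added for log2 CPM. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with the same block, with Benjamini-Hochberg over the lists with at least 3 tested members (16 in X. laevis, 14 in X. tropicalis). Camera with an estimated correlation was run beside it. The expected overlap of independent lists is the product of their sizes over the number of models tested in both. Level ratios that include models tested in 1 species alone have levels set to at least 3 counts over the libraries of a species. Figures were drawn with matplotlib 3.10.9.

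The design, the 17 gene lists and the rule for named genes were set before the data were examined. Named genes are, per species, the 8 vegetal and 8 animal genes with the largest fold change among those enriched, with 1 direction in every pair, a mean of at least 5 CPM and a symbol that is not a clone or locus number. They also include every tested member of the known vegetal and known animal lists and at most the 2 called members with the lowest adjusted p of each other list. For the species interaction they are the 5 largest differences in each direction with at least 5 CPM in both species, and for the female interaction the 3 lowest adjusted p, of which none passed. Some genes under this rule are not reported here. List members beyond this rule are printed as examples chosen after their values were seen. The known lists rest on general knowledge of Xenopus oocytes and not on these libraries. Of their 22 vegetal and 9 animal entries, 20 and 8 were found in the annotation by symbol. The annotation's synonyms were not searched, and pgat was among the vegetal entries not found.

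On simulated counts with 200 changed genes, and with calls at an adjusted p under 0.05 without the fold limit, the X. laevis test recovered 87 of 97 genes changed 2-fold and 95 of 96 changed 4-fold, with 24 unchanged models called (5 of them at least 2-fold). The X. tropicalis test recovered 84 of 98 and 95 of 96, with 15 unchanged models called (3 at least 2-fold). The species interaction recovered 62 of 100 and 90 of 95, with 10 unchanged models called (4 at least 2-fold). The female interaction recovered 30 of 100 and 71 of 99, with 9 unchanged models called (9 at least 2-fold). In each test, unchanged models made up more of the calls than the adjusted p limit of 0.05 allows. The simulated counts were drawn with the fitted spread of each model. Alternatives were RLE factors, library totals, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, no replicate block, the female as block, batches summed per female, a fold of at least 4, glmTreat against 1.5-fold and leaving out each batch or library. Added after the data were seen were X. laevis with 1 batch per female thinned to the X. tropicalis totals, and X. laevis batches A_t1 and B_t2 or A_t2 and B_t1 alone.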

Results

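The series compared RNA from the animal and vegetal hemispheres of Xenopus oocytes in 2 frog species. The animal hemisphere is the pigmented side that holds the nucleus, and the vegetal hemisphere is the yolk-rich side whose cortex holds the germ plasm. The X. laevis part holds 8 libraries from stage VI oocytes, 4 animal and 4 vegetal, from females A and B with 2 batches each (A_t1, A_t2, B_t1 and B_t2). The X. tropicalis part holds 4 libraries, 2 animal and 2 vegetal, from females 1 and 2. The total counts of the X. laevis animal libraries were 40830528 (A_t1), 39137832 (A_t2), 30416352 (B_t1) and 44157292 (B_t2). Those of the X. laevis vegetal libraries were 35565052 (A_t1), 45235154 (A_t2), 37193423 (B_t1) and 40753768 (B_t2). The X. tropicalis animal libraries held 11768136 (female 1) and 28392285 counts (female 2), and the vegetal libraries 7772801 and 21699080. A count of 0 in a single library allowed a level of up to 0.0986 counts-per-million (CPM) in X. laevis and up to 0.386 CPM in X. tropicalis. These limits cover counting error only.

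The first question was which transcripts are enriched in the vegetal or in the animal hemisphere of X. laevis oocytes. Among expressed X. laevis genes with a symbol, grip2 had the largest vegetal enrichment. The mRNA of grip2 (model Xetrov72008424), a PDZ domain protein of the germ plasm, rose from 4.15 ± 0.386 CPM in animal to 1368 ± 330 CPM in vegetal libraries (mean ± SD, n = 4), a log2 fold change of 8.35 ± 0.16 (SE, 4 pairs) or 325-fold. Among the same genes, the germline translational repressor nanos1 (Xetrov72027613) followed with a log2 fold change of 7.48 ± 0.26 and rose from 0.516 ± 0.215 to 94.7 ± 35.1 CPM. The Wnt ligand wnt11b (5.65 ± 0.20), the ubiquitin ligase trim36 (5.41 ± 0.22), the TGF-beta family ligand gdf1, also known as Vg1 (5.34 ± 0.25), and the germ cell RNA-binding protein dazl (5.09 ± 0.20) were all more than 16-fold vegetal. The remaining members of the top 8 were slain1, a microtubule-associated protein (6.01 ± 0.17), and snai1, a zinc finger repressor (5.06 ± 0.19). All 8 were higher in the vegetal library of each of the 4 pairs, which the rule for named genes required. Their adjusted p lay between 4.12e-07 and 8.59e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg).

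Animal enrichments of expressed, named X. laevis genes were smaller. Among the largest were those of the myosin phosphatase partner mprip (-3.06 ± 0.14), xkrx (-2.95 ± 0.18), fam82a2 (-2.82 ± 0.18), the vesicular monoamine transporter slc18a2 (-2.80 ± 0.16), the tyrosine phosphatase ptpn9 (-2.60 ± 0.13), the ADP-dependent glucokinase adpgk (-2.56 ± 0.15) and the sulfotransferase chst10 (-2.51 ± 0.17), as log2 fold changes. All 7 were lower in the vegetal library of each of the 4 pairs, which the rule for named genes required. Their adjusted p lay between 8.56e-06 and 4.24e-05 (edgeR, Benjamini-Hochberg). Of 14517 gene models tested in X. laevis, 437 were vegetal-enriched and 519 animal-enriched at an adjusted p under 0.05 and at least 2-fold. In all 4 pairs, 425 of the 437 and 518 of the 519 had the direction of the call. Without the fold limit, 1922 models were higher in vegetal and 2095 in animal libraries, a vegetal share of 47.8%. Scaling by library totals alone moved that split to 1442 and 2619 (35.5%). At least 4-fold, 163 models were vegetal-enriched and 101 animal-enriched. The animal count moved with the batches: it was 465 with batches A_t1 and B_t2 alone and 1025 with A_t2 and B_t1 alone, and it fell to 302 among models with a mean of at least 5 CPM.

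The X. laevis members of the list of known vegetal mRNAs were all vegetal-enriched. All 20 tested members passed the test at more than 2-fold and all 20 were positive in every pair, with a lowest single-pair log2 value of 1.54. All 20 also passed when adjusted over the list alone. The median log2 fold change was 4.11, and camera with its preset correlation gave an adjusted p of 8e-27 for the list (adjusted p = 0.192 with an estimated correlation). Examples were the T-box factor vegt, which specifies endoderm and mesoderm, with a log2 fold change of 4.23 ± 0.19 (85.3 ± 25.8 to 1557 ± 221 CPM), the germ plasm helicase ddx25 (4.93 ± 0.19), the germ cell factor dnd1 (4.35 ± 0.17) and sybu, also known as syntabulin (4.71 ± 0.20). The most abundant, the lipid droplet protein plin2, rose from 846 ± 60.9 to 3796 ± 516 CPM (2.16 ± 0.11), and rbpms2 had the smallest enrichment (1.77 ± 0.10). The list of known animal mRNAs was mixed. Of its 8 tested members, 3 were at least 2-fold animal: the ectodermal factor foxi2 (-1.54 ± 0.19), the Nodal inhibitor dand5 (-1.35 ± 0.16) and the epidermal factor grhl1 (-1.18 ± 0.15). The transcription factor zic2 was higher in vegetal libraries (0.35 ± 0.08, adjusted p = 0.0174, edgeR, positive in all 4 pairs; adjusted p = 0.0853 without batch A_t2), while ddx3x (-0.30 ± 0.19), trim33 (-0.03 ± 0.09), atp5a1 (-0.04 ± 0.11) and foxi1 (0.69 ± 0.32) were not called. Adjusted over the list alone, the counts were again 1 vegetal and 3 animal, and the list's camera adjusted p was 0.251.

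**Figure D1:**
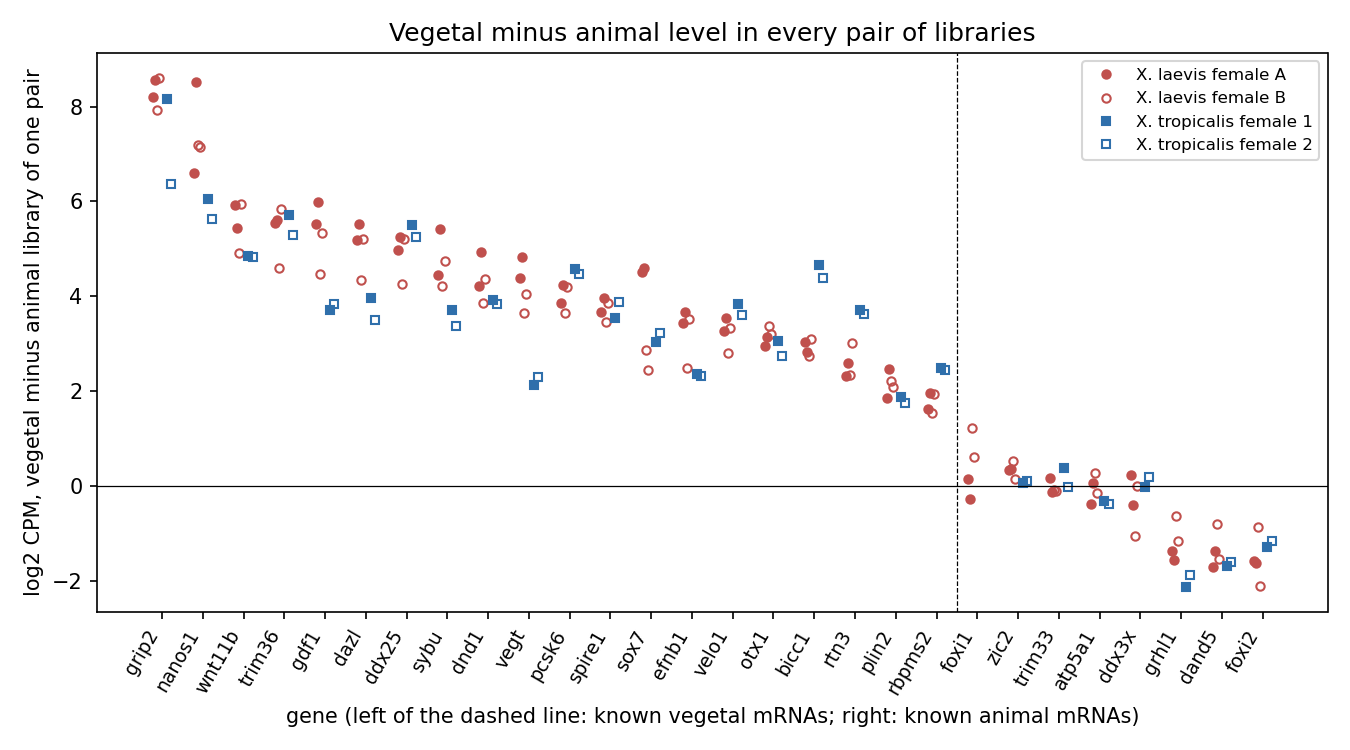
Vegetal minus animal level (log2 CPM, vertical axis) of each known vegetal mRNA (left of the dashed line) and known animal mRNA (right) in each pair of libraries; circles are the 4 X. laevis pairs (filled, female A; open, female B) and squares the 2 X. tropicalis pairs (filled, female 1; open, female 2). All 20 known vegetal mRNAs lie above 0 in every pair of both species, and foxi2, dand5 and grhl1 lie below 0 in every pair.

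Among the signalling lists in X. laevis, the TGF-beta and BMP pathway had 14 vegetal and 3 animal members of 33 tested (15 and 3 adjusted over the list alone). Besides gdf1, its vegetal members included the ligand gdf3, also known as derriere (5.62 ± 0.25, at 0.0919 ± 0.0304 CPM in animal and 4.84 ± 1.58 CPM in vegetal libraries), the proprotein convertase pcsk6 (3.99 ± 0.13), the inhibitory smad7 (1.62), the ligands bmp2 (1.05) and bmp15 (1.11) and the receptor acvr1 (1.04), of which gdf1 and pcsk6 are also on the list of known vegetal mRNAs. The animal members were dand5, the receptor tgfbr1 (-0.70) and the ubiquitin ligase smurf1 (-0.77). Its camera adjusted p was 0.00157 (adjusted p = 0.192 with an estimated correlation). The Wnt list had 7 vegetal and 3 animal members of 34, and its camera adjusted p was 0.229. The vegetal members included wnt11b, the nuclear effector tcf7l2 (1.73) and the signal transducer ctnnb1 (0.46), and the animal ones were the receptor fzd4 (-1.06 ± 0.12), the destruction complex protein apc (-0.69) and axin1 (-0.40). Counts adjusted over the Wnt list alone were also 7 and 3.

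Several lists of oocyte functions were split between the hemispheres of X. laevis. The meiosis and cell cycle list had 15 vegetal and 4 animal members of 35 (16 and 4 adjusted over the list alone), with camera adjusted p = 0.0073 (adjusted p = 0.465 with an estimated correlation). The antiproliferative factor btg4 (0.70 ± 0.08), cdc6 (0.99) and ccnb1 (0.58) were vegetal, and the MAP kinase kinase map2k1 (-1.40 ± 0.11) and the mitotic kinase aurka (-1.17) were animal. The oocyte translation control list had 10 vegetal and 3 animal members of 29 (14 and 3 adjusted over the list alone), with camera adjusted p = 0.00523 (adjusted p = 0.192 with an estimated correlation). Its vegetal members included tob2 (2.93 ± 0.28), the RNP granule protein lsm14b (1.80 ± 0.13) and the deadenylase parn (1.39), and the animal ones the repressor pum2 (-0.53). The piRNA and nuage list leaned the other way, with 1 vegetal and 7 animal members of 19 (2 and 7 adjusted over the list alone), the latter including tdrkh (-1.01 ± 0.14), tdrd5 (-0.75 ± 0.09) and piwil1 (-0.85). Its camera adjusted p was 0.0153 (adjusted p = 0.442 with an estimated correlation). In batches A_t2 and B_t1 this list's median was lower than in A_t1 and B_t2 (-0.479 and -0.575 against -0.185 and -0.112). The vegetal RNA transport factors had 2 vegetal and 6 animal members of 19, again 2 and 6 adjusted over the list alone (camera adjusted p = 0.255), and the animal ones included the dynactin subunit dctn1 (-1.05 ± 0.11) and the RNA-binding protein ptbp1 (-0.84 ± 0.09).

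Most members of each of the remaining X. laevis lists were not called. Of 74 cytosolic ribosomal protein mRNAs, 2 passed the test, both vegetal (rps12 at 0.47 ± 0.13 and rpl26 at 0.51 ± 0.14). Neither of the pair passed without batch A_t2 or without batch B_t2, and none passed when adjusted over the list alone. The list's median was 0.125 with camera adjusted p = 0.017 (adjusted p = 0.819 with an estimated correlation), but its medians per batch were -0.253 (A_t1), 0.260 (A_t2), 0.564 (B_t1) and -0.0231 (B_t2). Of 48 nuclear-encoded OXPHOS mRNAs, 6 were animal and 0 vegetal (5 and 0 adjusted over the list alone), such as atp5c1 (-0.48 ± 0.08) and sdhd (-0.43 ± 0.08, not called without batch A_t2). The OXPHOS medians per batch were -0.341 (A_t1), 0.0601 (A_t2), 0.267 (B_t1) and -0.145 (B_t2), and the camera adjusted p was 0.297. Of 8 tested members of the vitelline envelope list 3 were vegetal (4 adjusted over the list alone), led by zp2 (0.61 ± 0.08) and zp4 (0.49 ± 0.08), with camera adjusted p = 0.0737. That list also holds zar1, a member of the translation control list. The keratin and cytoskeleton list had 6 vegetal and 3 animal members of 25 (8 and 3 adjusted over the list alone), the latter led by the microtubule-associated map4 (-1.64 ± 0.08) and the septin sept2 (-1.01 ± 0.08), and its camera adjusted p was 0.579. Under scaling by library totals its median of 0.042 turned to -0.0308 and its calls to 3 vegetal and 5 animal. The 1 measured mitochondrial genome transcript was not called (-0.755). Most markers of other cell types were low, with median levels between 0.642 CPM (follicle cell markers) and 1.52 CPM (blood and endothelial markers). Of 8 tested follicle cell markers only the steroid hydroxylase cyp17a1 was called, and it was vegetal (1.51 ± 0.15, 118 ± 35.3 to 325 ± 29.2 CPM). Its level lay far over the list's median of 0.642 CPM. That level does not tell whether it came from follicle cells, and its source was not tested. Of 7 connective tissue markers only fn1 was called (0.76 ± 0.11), of 9 blood and endothelial markers kdr (-1.57 ± 0.26) and slc4a1 (0.49 ± 0.11), and of 7 immune markers csf1r (-0.86 ± 0.23). Neither slc4a1 nor csf1r was called without batch A_t2 or without batch B_t2. The camera adjusted p of these 4 lists were 0.442, 0.932, 0.718 and 0.501, and adjusted over each list alone the same numbers of markers passed.

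The same question was asked in X. tropicalis. Its largest vegetal enrichments among expressed, named genes were those of grip2 (6.90 ± 0.10, from 5.26 ± 3.23 to 759 ± 174 CPM, mean ± SD, n = 2), pat (6.13 ± 0.09, from 4.71 ± 1.75 to 353 ± 17.3 CPM) and nanos1 (5.77 ± 0.10). They were followed by trim36 (5.47 ± 0.08), ddx25 (5.36 ± 0.08), the acyltransferase mogat1 (4.89 ± 0.09), the phospholipase pld2 (4.86 ± 0.17) and wnt11b (4.85 ± 0.08). The largest animal enrichments among expressed, named genes were those of the receptor phosphatase ptprq (-5.86 ± 0.23, 26.8 ± 0.627 CPM animal, 0.391 ± 0.183 CPM vegetal) and menf.2 (-5.34 ± 0.21). Next came gdap2 (-2.47 ± 0.11), the actin-associated smtn (-2.28 ± 0.07), slc18a2 (-2.14 ± 0.07), fam82a2 (-2.12 ± 0.07), the nucleoporin nup210 (-2.12 ± 0.13) and the nucleotide sugar transporter slc35d1 (-2.07 ± 0.16). All 16 had the same direction in both pairs, which the rule for named genes required. With 1 library left out and no block, the calls of gdap2, nup210 and slc35d1 were lost in 2, 3 and 3 of the 4 fits, each time including both fits without a vegetal library, with log2 values from -2.86 to -2.08, -3.09 to -1.04 and -2.69 to -1.43 over the 4 fits. Their adjusted p lay between 2.18e-120 and 1.69e-24 (edgeR, Benjamini-Hochberg), with 1 residual degree of freedom per gene and a prior of 162, so that these p-values rest almost entirely on the spread pooled across genes.

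Of 12916 models tested in X. tropicalis, 425 were vegetal-enriched and 469 animal-enriched at least 2-fold, and 424 and 468 of them had that direction in both pairs. Without the fold limit the counts were 2020 and 2236, a vegetal share of 47.5%, which scaling by library totals alone moved to 1436 and 2743 (34.4%). At least 4-fold, 164 were vegetal-enriched and 107 animal-enriched. The counts depended on the female as a block. Without the block they were 172 vegetal and 84 animal. With no block and also 1 library left out, they were 319 and 217 (without the animal library of female 1), 280 and 258 (animal, female 2), 143 and 21 (vegetal, female 1) and 113 and 13 (vegetal, female 2), the lone library being assumed to vary like the others. The animal count was also 282 with DESeq2 and 238 among models with a mean of at least 5 CPM.

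In X. tropicalis all 20 known vegetal mRNAs were again more than 2-fold vegetal, over all genes and adjusted over the list alone, with a median of 3.73 and a lowest single-pair value of 1.76 (camera adjusted p = 5.67e-45, adjusted p = 0.742 with an estimated correlation). The RNA-binding protein bicc1 (4.51 ± 0.07), dazl (3.70 ± 0.07), gdf1 (3.79 ± 0.08) and vegt (2.25 ± 0.11, from 11.9 ± 2.03 to 56.1 ± 13.8 CPM) were among them. Of 7 known animal mRNAs, grhl1 (-1.97 ± 0.14), dand5 (-1.68 ± 0.23) and foxi2 (-1.20 ± 0.15) were at least 2-fold animal, atp5a1 was animal at a lower size (-0.33 ± 0.06), and ddx3x (0.09 ± 0.06), zic2 (0.09 ± 0.06) and trim33 (0.10 ± 0.09) were not called. With 1 library left out and no block, efnb1, otx1 and vegt were not called in at least 1 of the 4 fits, nor were grhl1, dand5, foxi2 and atp5a1, while the other 17 known vegetal mRNAs were called in all 4. Adjusted over the list alone, again 4 animal members passed, and the list's camera adjusted p was 0.0718.

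The other X. tropicalis lists with a camera adjusted p under 0.05 were oocyte translation control, OXPHOS and vitelline envelope genes. Translation control had 10 vegetal and 3 animal members of 28, again 10 and 3 adjusted over the list alone, led by the poly(A)-binding protein pabpc1l (0.84 ± 0.06) and parn (0.80 ± 0.06), with camera adjusted p = 0.0276 (adjusted p = 0.742 with an estimated correlation). OXPHOS mRNAs were animal in 20 and vegetal in 1 of 48 (21 and 1 adjusted over the list alone), led by uqcrc2 (-0.58 ± 0.07) and ndufs7 (-0.55 ± 0.07), with camera adjusted p = 0.0162 (adjusted p = 0.921 with an estimated correlation). Of 8 tested members of the vitelline envelope list, which shares zar1 with the translation control list, 5 were vegetal (6 adjusted over the list alone). They were led by zp3 (1.38 ± 0.06) and zp2 (0.98 ± 0.06), with camera adjusted p = 0.000715 for the list (adjusted p = 0.742 with an estimated correlation). With 1 library left out and no block, the calls of uqcrc2 (-0.624 to -0.511) and ndufs7 (-0.779 to -0.252) were lost in all 4 fits, those of pabpc1l (0.788 to 0.903) and parn (0.613 to 0.992) without the animal library of female 2 or either vegetal library, that of zp2 (0.985 to 1.00) without either vegetal library and that of zp3 (1.22 to 1.56) without the vegetal library of female 1.

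The camera test called none of the other X. tropicalis lists at an adjusted p under 0.05. Meiosis and cell cycle had 13 vegetal and 8 animal members of 34 (15 and 9 adjusted over the list alone, camera adjusted p = 0.706), with the lowest adjusted p for aurka (-1.56 ± 0.06) and the checkpoint kinase bub1 (-1.43 ± 0.06), both animal. The list's median (0.0649) and mean (-0.0542) differed in sign. TGF-beta and BMP had 8 vegetal and 5 animal members of 31 (camera adjusted p = 0.0977), with gdf1 (3.79), pcsk6 (4.53 ± 0.09), bmp2 (0.78) and bmp15 (0.89) vegetal and the receptor bmpr2 (-2.19) animal. Wnt had 9 and 4 of 30 (camera adjusted p = 0.166), with tcf7l2 (1.85), the receptor fzd1 (1.31) and the kinase csnk1a1 (0.63 ± 0.06) vegetal, and its median of 0.0431 turned to -0.0166 under library totals. The piRNA and nuage list had 0 vegetal and 7 animal members of 19 (camera adjusted p = 0.0818), with the lowest adjusted p for gtsf1 (-0.56 ± 0.06) and tdrkh (-0.37 ± 0.06). Transport factors had 5 and 4 of 20 (camera adjusted p = 0.706), with the kinesin kif3b vegetal (2.30-fold) and khsrp animal (-0.64 ± 0.06), and their median of 0.0216 turned to -0.0384 under library totals. These 4 lists had the same counts adjusted over the list alone. Ribosomal protein mRNAs had 17 vegetal and 6 animal members of 73 (again 17 and 6 adjusted over the list alone, camera adjusted p = 0.0845), with the lowest adjusted p for rpl18 (-0.54 ± 0.06) and rpl10a (-0.42 ± 0.06), and under library totals their calls turned to 9 vegetal and 14 animal. The keratin and cytoskeleton list had 6 vegetal and 6 animal members of 22, again 6 and 6 adjusted over the list alone (camera adjusted p = 0.91), with krt8 (1.77 ± 0.06) and the contractile ring protein anln (1.62 ± 0.06) vegetal; its median of 0.0283 turned to -0.0321 under library totals. Of the cell type markers, fn1 (0.29 ± 0.08) and cd74 (-1.22 ± 0.48) were called among 3 connective tissue and 2 immune markers, and none among 3 blood and endothelial markers (camera adjusted p = 0.878 and 0.892 for the connective tissue and blood lists). The 1 tested follicle cell marker (0.054) and the 1 mitochondrial genome transcript (0.162) were not called. With 1 library left out and no block, the calls of tdrkh, khsrp, rpl10a, fn1 and cd74 were lost in all 4 fits. Those of csnk1a1 and rpl18 were lost without the animal library of female 2 or either vegetal library, that of gtsf1 without the animal library of female 1 or either vegetal library, and those of bub1, kif3b and anln without either vegetal library. The call of krt8 was lost without the vegetal library of female 1 and that of aurka without that of female 2. All 13 kept their direction in each of these fits, with the widest ranges for csnk1a1 (0.229 to 1.1) and rpl18 (-0.862 to -0.203).

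**Figure D2:**
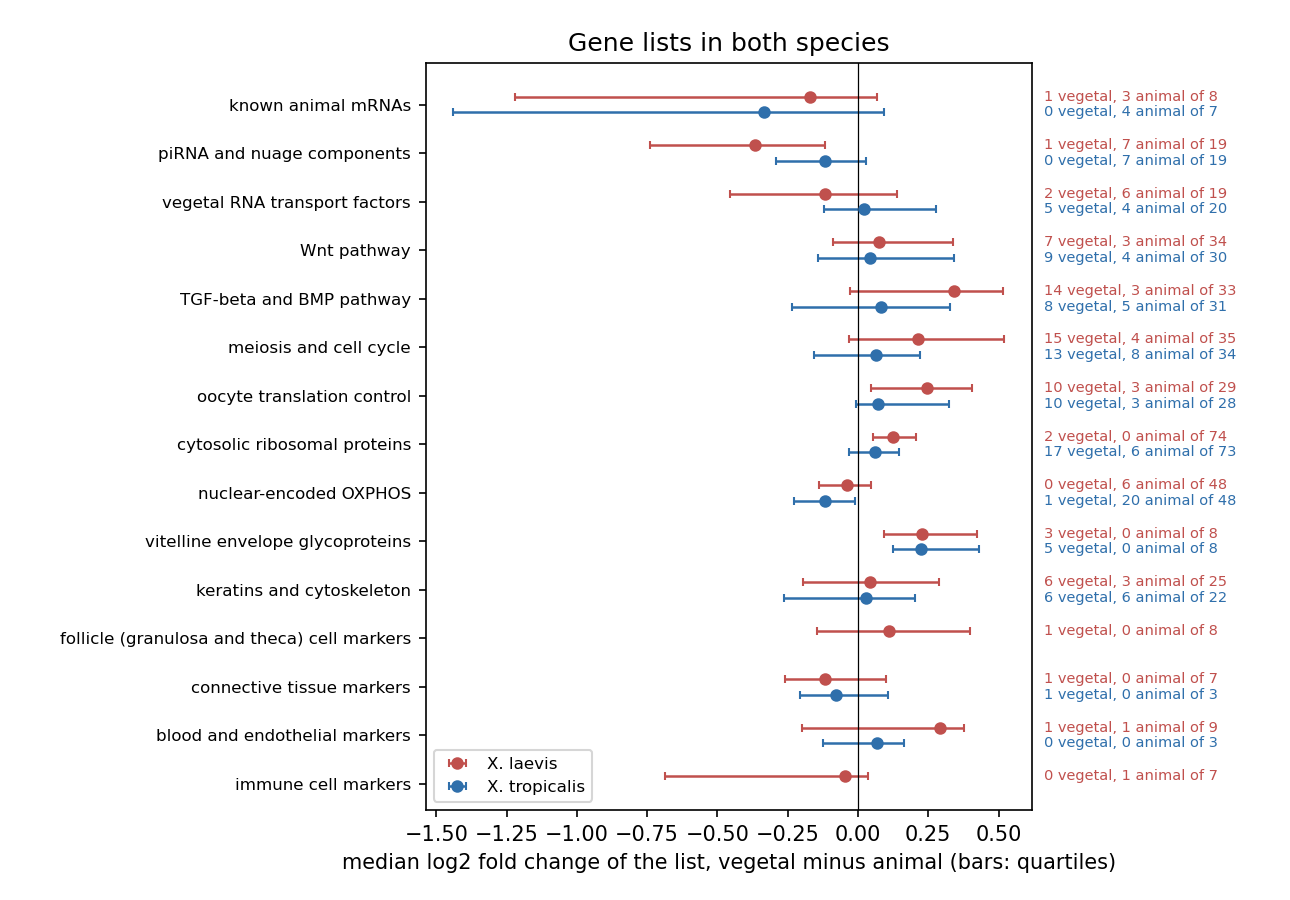
Median log2 fold change (vegetal minus animal, horizontal axis) of each gene list with at least 3 tested members in X. laevis (red) and X. tropicalis (blue), with bars from the lower to the upper quartile; the text at the right gives the members called vegetal and animal at an adjusted p under 0.05. The list of known vegetal mRNAs (medians 4.11 and 3.73) is left out for scale. The medians of the Wnt list and transport factors in X. tropicalis and of the keratin list in both species change sign under scaling by library totals.

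The next comparison asked how far localization is shared between the species. Among 11688 models tested in both, 156 were vegetal-enriched in both, against 10.5 for independent lists. They made up 45.2% of the 345 vegetal models of X. laevis and 43.8% of the 356 of X. tropicalis. Besides the tested members of the known list, they included mov10 (4.19 in X. laevis, 4.40 in X. tropicalis), the growth factor receptor fgfr2 (4.11 and 4.02), acsl1 (4.14 and 3.48), slc12a9 (3.46 and 3.68) and pat (4.09 and 6.13), chosen after their values were seen except for pat. Whether pat is the listed pgat, which was not found by symbol, was not checked. Animal enrichment was shared by 92 models, against 11.6 for independent lists, of 370 in X. laevis and 368 in X. tropicalis. Among these were smtn (-2.42 and -2.28), slc18a2 (-2.80 and -2.14), fam82a2 (-2.82 and -2.12), nup210 (-1.88 and -2.12) and ptprq (-2.96 and -5.86). At least 4-fold in both, 58 models were vegetal, against 1.58 for independent lists. Across genes, which are not independent replicates, the fold changes of the species had a Pearson correlation of 0.506 and a Spearman correlation of 0.34. Without the replicate block, the number of shared vegetal models was 88, against 4.63 for independent lists.

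Differences between the species were tested as an interaction of hemisphere and species. The acyltransferase mogat1 was vegetal in X. tropicalis (4.89) and nearly even in X. laevis (0.29), a difference of -4.63 ± 0.20 (X. laevis minus X. tropicalis, log2 ± SE, 4 and 2 pairs). The phospholipase pld2 (0.59 and 4.86, difference -4.28 ± 0.17), pxk (-0.18 and 3.80, -3.94 ± 0.18) and the mitochondrial carrier slc25a22 (0.61 and 4.02, -3.44 ± 0.33) were also far more vegetal in X. tropicalis. The X. laevis value of tmem54 lay on the animal side (-0.80 against 2.52, -3.33 ± 0.37) and moved by 1.09 between batches A_t1 and B_t2 and batches A_t2 and B_t1 (edgeR adjusted p = 0.031). In the other direction, tmem82 was vegetal in X. laevis (3.41) and not in X. tropicalis (-0.12), a difference of 3.55 ± 0.22. The glycolytic enzyme pgam1 (3.99 and 0.55, 3.44 ± 0.22), the GTPase arl9 (3.49 and 0.09, 3.39 ± 0.16) and trank1 (3.45 and 0.29, 3.18 ± 0.40) followed it. The carrier slc25a34 was vegetal in X. laevis (1.73) and animal in X. tropicalis (-1.65), a difference of 3.38 ± 0.32. The adjusted p of these 10 genes lay between 1.38e-05 and 0.00171 (edgeR, Benjamini-Hochberg).

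In all, 1457 models differed between the species, 783 more vegetal in X. laevis and 674 more vegetal in X. tropicalis, and 658 of them by at least 2-fold. Of the models vegetal-enriched in X. laevis only, 138 of 189 passed the interaction test, as did 157 of the 200 vegetal-enriched in X. tropicalis only. Of all 11688 models tested in both, 1457 passed in either direction. Both groups were picked from the same libraries for a call in 1 species alone, which favours a pass. The fold limit sets part of these groups: 72 of the 189 and 67 of the 200 were also higher in vegetal libraries of the other species at an adjusted p under 0.05, but by less than 2-fold. Vegetal enrichment found in both species also differed in size: vegt (4.23 against 2.25, adjusted p = 0.00398) and snai1 (5.06 against 2.69, adjusted p = 0.00184) were more vegetal in X. laevis, and bicc1 (2.93 against 4.51, adjusted p = 0.000415) more vegetal in X. tropicalis (edgeR, chosen after their values were seen). X. laevis counts carry X. tropicalis model identifiers with no separate values for homeologous copies. Whether the reads were aligned to the X. tropicalis genome or to X. laevis sequences is not given in the sources used here, so part of a difference can come from how reads were assigned. The number of models called moved with the block and the libraries: it was 458 without the replicate block, 357 without X. tropicalis female 1, 292 without female 2, 872 without batch A_t2, 2825 with X. laevis batches A_t1 and B_t2 alone, 3457 with A_t2 and B_t1 alone and 3685 with the X. laevis batches summed per female. Without 1 X. tropicalis female, that species has a single pair and the spread comes from the X. laevis pairs alone.

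**Figure D3:**
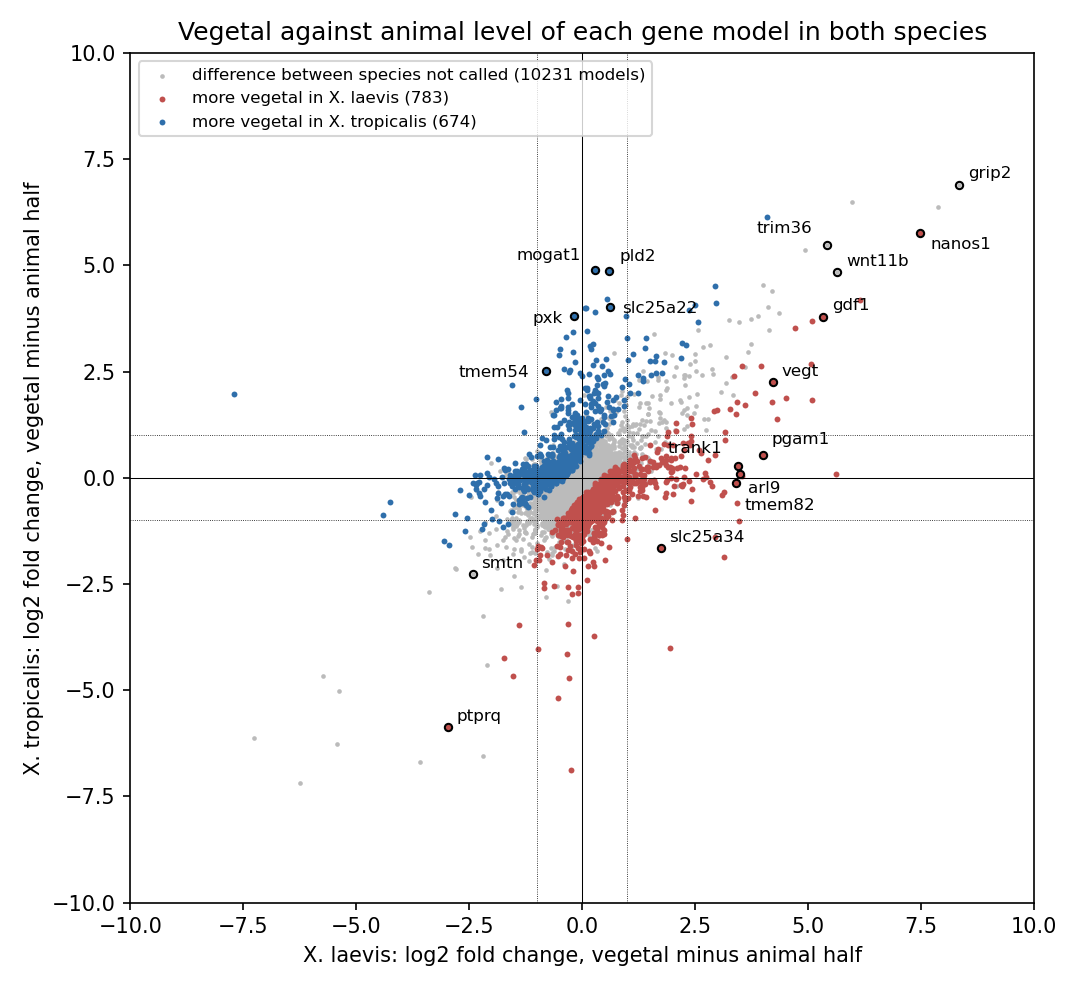
Log2 fold change (vegetal minus animal) of each of 11688 gene models in X. laevis (horizontal axis) and X. tropicalis (vertical axis); grey, no difference called between the species; red, 783 models more vegetal in X. laevis; blue, 674 more vegetal in X. tropicalis (adjusted p under 0.05). Dotted lines mark 2-fold. Germ plasm mRNAs such as grip2 and nanos1 lie at the upper right, mogat1 and pld2 near the vertical axis and tmem82 and arl9 near the horizontal axis.

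The last comparison asked whether the X. laevis enrichments differed between the females. The interaction of hemisphere and female called 0 of 14517 models with edgeR, 4 with DESeq2 and 254 at an unadjusted p under 0.05. Fitted within each female, 459 models were vegetal-enriched in female A and 435 in female B, of which 345 were the same, and 578 and 526 were animal-enriched, of which 326 were the same. The fold changes of the females had a Pearson correlation of 0.876 across 13850 genes, which are not independent replicates. The known vegetal list had medians of 4.31 and 4.71 in the batches of female A and of 3.64 and 4.12 in those of female B. Leaving out batch A_t1, A_t2, B_t1 or B_t2 gave 1, 13, 19 and 212 models that differed between the females, with 1 pair left for a female and the spread taken from the other female alone. In simulated data with this design, 30 of 100 genes with a 2-fold and 71 of 99 genes with a 4-fold difference between the females were recovered.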

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

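The tests of low counts, nuclear RNA, merged copies and the level of models tested in 1 species alone, and those of depth, animal material and RNA quality in batches A_t2 and B_t1, were chosen after the results were seen.

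Localization that differs between the species was singled out because an interaction test showed it. It covered 1457 models. The largest differences with enough expression (log2, X. laevis minus X. tropicalis) were those of tmem82 (3.55), pgam1 (3.44), arl9 (3.39), slc25a34 (3.38) and trank1 (3.18) on the X. laevis side. On the X. tropicalis side they were those of mogat1 (-4.63), pld2 (-4.28), pxk (-3.94), slc25a22 (-3.44) and tmem54 (-3.33). Of the 15 splits of the 6 pairs into 4 and 2, the split by species alone (1 split) gave as many as 1457 models, and the highest other gave 328. With 15 splits, a share under 0.05 cannot be reached. The other splits mix the species, so a species difference enters their spread and their counts are no measure of chance.

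For models vegetal-enriched in 1 species only, 3 technical explanations were weighed. If X. laevis reads were lost on the X. tropicalis models, models vegetal in X. tropicalis only would have lost X. laevis level. For the 200 of them tested in both species, the median log2 level ratio lay 0.556 below that of models vegetal in both (95% interval 0.155 to 0.97). This bound covers the median of models that passed the X. laevis filter, which a large loss would fail. Their lower quartile was -1.87, against -1.04 for models vegetal in both, so a loss of 1 log2 or more stays open for part of them. With the 69 models not tested in X. laevis the drop was 1.37 (0.818 to 1.82), so a larger loss stays open for these. Models vegetal in X. laevis only lay 1.43 above those vegetal in both (0.908 to 2.08, with 92 not tested in X. tropicalis). Without the 92, the median ratio was 0.434 against -0.0509. Models that a species does not test are low there, so adding them moves both ratios by selection. Lost X. laevis reads were thus neither shown nor ruled out. A different height of dissection in 1 species would move most vegetal RNAs one way, but of 53 models vegetal in both and called different, 27 were more vegetal in X. laevis and 26 in X. tropicalis (50.9%, interval 36.8 to 64.9). Merged L and S copies cannot be told apart from the species: both copies were found for 59.4% of matched genes vegetal in X. tropicalis only and for 67.4% of those vegetal in both, a difference of -8.02 points whose interval (-20.6 to 4.59) holds 0. A difference in biology between the species stays open and untested, for slc25a34 and mogat1 as for the other models.

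In single libraries, 7 values of named genes lay far from the rest of their group. These were snai1 in animal B_t1 (1.4 CPM, others 0.672 to 0.733), plin2 in animal A_t1 (937, others 814 to 817), atp5c1 in animal A_t1 (412, others 348 to 358) and slc4a1 in animal A_t1 (5.67, others 7.97 to 8.44). The others were csf1r in animal A_t2 (1.15, others 0.952 to 0.962), ptpn9 in vegetal A_t2 (22, others 31.9 to 33.3) and gdf3 in vegetal A_t2 (7.2, others 3.88 to 4.25). Chance gives 6.1 such values in the 122 groups examined.

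In X. laevis, the hemisphere comparison gave 437 vegetal-enriched and 519 animal-enriched models. Of the 8 splits of the 8 libraries that part all 4 batches, the real one (1 split) gave the most, and the highest other gave 0 on either side. A share under 0.05 cannot be reached with 8 splits. The other splits swap the hemispheres in some batches, so the hemisphere difference enters their spread and their 0 is no measure of chance. The comparison of the females called 0 models in edgeR (254 at an unadjusted p under 0.05, and 4 with DESeq2), and a share under 0.05 cannot be reached with 3 splits of the 4 batches into pairs. The split of A_t1 and B_t2 against A_t2 and B_t1 called 555 models, which points to a structure of the samples that does not follow the females.

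That structure lay in the vegetal libraries of A_t2 and B_t1, where 462 of the 555 models were lower, with a mean log2 CPM of 3.80 and 3.58 against 4.77 and 4.55 in vegetal A_t1 and B_t2 and 4.57 to 4.86 in the animal libraries, and 41 of the 519 animal-enriched models were among them. A lower depth of both vegetal libraries was argued against, since vegetal A_t2 had the highest total of the vegetal libraries (45.2 M counts). Depth within pairs stays open. The vegetal total was above the animal total in A_t2 (45.2 against 39.1 M) and B_t1 (37.2 against 30.4 M). It was below the animal total in A_t1 (35.6 against 40.8 M) and B_t2 (40.8 against 44.2 M). Animal material in vegetal A_t1 and B_t2 would have to make up most of those libraries to lift the 462 models to the animal level, and this was excluded, since the 20 known vegetal mRNAs kept a median log2 ratio of 4.12 there (lower quartile 3.25) against 4.09 in A_t2 and B_t1; a smaller share stays open. A difference in RNA quality or library preparation stays open. The vegetal enrichment in A_t1 and B_t2 minus that in A_t2 and B_t1 had medians of -0.546 for ribosomal protein mRNAs (random lists -0.154 to 0.0143) and -0.44 for OXPHOS mRNAs (random lists -0.157 to 0.0609). Both classes were thus more vegetal in A_t2 and B_t1, opposite to the 462 models. Members of these 2 lists move together (camera's estimated correlations 0.966 and 0.757), unlike those of random lists. Medians outside the random range therefore cannot decide on this cause. Of the other lists, blood and endothelial markers (-0.409) lay outside their random range on the same side, and piRNA (0.202) and known vegetal mRNAs (0.114) on the other; the labels name neither RNA quality nor preparation day, and no biological explanation was tested.

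The last pattern is the low abundance of the strongest animal enrichments, at least 16-fold by fitted values. In X. laevis 21 of 23 such models lay under 5 CPM, against 6 of 28 on the vegetal side, and in X. tropicalis 40 of 44 against 2 of 21. Of the animal ones, 3 and 15 had 0 vegetal counts, so the size of their fitted fold is not measured. Cells of other types attached to the animal hemisphere were argued against for the types tested, since the follicle, connective tissue, blood and immune markers under 5 CPM had median log2 values of -0.0396 in X. laevis (25 markers, lower quartile -0.51) and -0.0767 in X. tropicalis (7 markers, lower quartile -0.327), though the called ones among them were all animal (2 in X. laevis, 1 in X. tropicalis) and the lowest values were -1.69 and -1.22, so a small share of such cells stays open. Noise of low counts as the cause was argued against. Models under 5 CPM were picked as at least 16-fold animal in 1 female by log2 CPM with the prior count of 2, not by fitted values. Of the picked models, 12 of 12 in X. laevis and 20 of 20 in X. tropicalis were animal in the other female (100%, lower bounds 73.5 and 83.2), with median log2 values of -3.25 and -3.80 there. These hold 9 of the 21 and 18 of the 40 models, so noise stays open for single models outside them, except that 5 models, with Xetrov72026811 the most abundant (15.7 and 7.57 CPM in animal libraries), were at least 16-fold animal in both species, against 0.011 for independent lists. RNA kept in the nucleus, which lies in the animal hemisphere, may be the source: 91.3% of the models in X. laevis and 84.1% in X. tropicalis had no symbol, against 43.1% and 41.3% for models of like abundance, but without a nuclear fraction this stays open.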

How the results depend on the processing

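The tests with 1 batch per female thinned to the X. tropicalis totals and with batches A_t1 and B_t2 or A_t2 and B_t1 alone were chosen after the results were seen.

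Known vegetal mRNAs kept their direction under every alternative that was run in both species. In X. laevis, grip2, vegt, nanos1 and the other known vegetal mRNAs also stayed past the threshold in each. Across 128 results for named genes and 1734 alternative values, 1565 kept their direction and their side of the threshold, 154 kept the direction and lost the call, 2 gained a call and 13 changed sign. The losses came with no replicate block (28), glmTreat against 1.5-fold (23), the X. tropicalis libraries left out 1 at a time (11 and 15 for animal libraries 1 and 2, 26 and 27 for vegetal libraries 1 and 2), thinning (9), the loss of A_t2 (6) or B_t2 (4), DESeq2 (3), no filter (1) and A_t1 and B_t2 alone (1).

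The sign changes all fell on known animal mRNAs that the main test had not called. In X. laevis they were ddx3x (0.15) and trim33 (0.0532) with A_t1 and B_t2 alone, atp5a1 with A_t2 and B_t1 alone (0.18) and trim33 with thinned counts (0.0175). With 1 batch left out, trim33 ranged from -0.0803 to 0.0156 and atp5a1 from -0.126 to 0.0789. In X. tropicalis with 1 library left out, ddx3x ranged from -0.20 to 0.42, zic2 from -0.13 to 0.30 and trim33 from -0.80 to 1.29. Calls were gained by ddx3x with A_t2 and B_t1 alone (-0.71) and atp5a1 with A_t1 and B_t2 alone (-0.24) in the edgeR test. The cause was not tested.

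Of the counts, X. laevis vegetal-enriched models stayed within 1.5 times 437 (302 to 517) under every alternative except the 4-fold limit (163), which by construction keeps fewer. X. laevis animal-enriched models (519) moved to 101 at 4-fold, 302 with a mean of at least 5 CPM, where fewer models are tested, and 1025 with A_t2 and B_t1 alone. Of those 1025, 461 were among the 519. X. tropicalis vegetal-enriched models (425) moved to 164 at 4-fold and 172 with no replicate block. X. tropicalis animal-enriched models (469) moved to 107 at 4-fold, 238 with at least 5 CPM, 282 with DESeq2 and 84 with no block. Leaving out 1 X. tropicalis library gave 113 to 319 vegetal-enriched and 13 to 258 animal-enriched models. These fits have no block and 1 library on one side, which is assumed to vary like the others.

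Models that differ between the species (1457) moved to 458 with no block, 2825 with A_t1 and B_t2 alone, 3457 with A_t2 and B_t1 alone and 3685 with batches summed per female, and ranged from 292 to 2014 with 1 replicate left out (where an X. tropicalis female is left out, the spread comes from X. laevis alone). The 3685 held all 1457. Models that differ between the females (0, and 254 at an unadjusted p under 0.05 in edgeR) moved to 4 with DESeq2 and to 1 to 212 with 1 batch left out. Models vegetal-enriched in both species (156) moved to 88 with no block and 58 at 4-fold, and the other alternatives gave 125 to 178. The cause of these changes was not tested. With 1 batch per female thinned to the X. tropicalis totals, X. laevis gave 360 vegetal-enriched and 422 animal-enriched models, against 437 and 519. In that fit, with fewer counts and libraries, rps12 and zp2 lost their calls and grip2 kept its call.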

Other observations

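Apart from smtn, nup210, slc25a34 and grip2, which follow the rule for named genes, the genes named in the first 3 paragraphs below were chosen after their values were seen. The test of function words was chosen before.

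Animal enrichment shared by both species was found for genes of several kinds. Among well expressed models, lima1, an actin-binding protein, was animal in X. laevis (-2.32, 524 CPM) and X. tropicalis (-1.79, 258 CPM), as were tmem57 (-1.88 and -1.59), smtn (-2.42 and -2.28) and nup210 (-1.88 and -2.12). The fatty acid synthesis enzyme acaca (-2.04 and -1.82), fnip2 (-1.68 and -1.62), snx27 (-1.53 and -1.80) and wdr62 (-1.47 in both) had the same direction. On the vegetal side, the shared models beyond the known list included the heparan sulfatase sulf1 (2.48 and 4.07), the lipoprotein receptor lrp1 (2.48 and 2.91), the kinesin kif13b (2.36 and 2.40) and the mitochondrial transport adaptor trak1 (2.18 and 2.82).

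Enrichment in opposite hemispheres was found for 10 models, 5 in each direction, beside the 156 vegetal and 92 animal models shared by both species. Among the 11688 models tested in both, the lists held 345 vegetal and 370 animal models in X. laevis and 356 and 368 in X. tropicalis. The number for independent lists was not computed for these 10, so whether they are fewer than such lists give was not tested. Named ones were the ARF exchange factor cyth2 (1.94 in X. laevis, and the most animal of the 10 in X. tropicalis), the antiviral factor rsad2 (3.14 and -1.86) and slc25a34 (1.73 and -1.65), vegetal in X. laevis, and the kinase camk2a (-1.02 and 1.87), vegetal in X. tropicalis. Their interaction adjusted p were 4.7e-05, 0.00202, 0.000416 and 0.00113 in edgeR. Several of these rest on low levels: cyth2 had 74.8 CPM in X. laevis and 1.72 CPM in X. tropicalis, rsad2 1.08 and 0.614 CPM, and camk2a 2.27 and 2.26 CPM.

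As a share of library counts, the grip2 level in animal libraries was 0.303% of the vegetal mean in X. laevis (0.256 to 0.407 over the libraries) and 0.694% in X. tropicalis (0.337 to 1.19).

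Words for gene function were tested against the vegetal-enriched and animal-enriched genes of each species, 64 tests in all. No word passed in both species on the same side (0 of 16 words). In X. laevis, "growth factor" passed on the vegetal side, with 8 genes against 1.96 for a random draw (Fisher adjusted p = 0.0392): wnt11b, gdf1, gdf3, bmp2, bmp15, nell2, angptl4 and erbb2, of which several are also on the known vegetal, TGF-beta or Wnt lists. In X. tropicalis the word had 3 vegetal genes, gdf1, wnt11b and acvr2b, against 1.5 (adjusted p = 0.664).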
